A study of Mus musculus with 9 samples.

How the data were processed

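RNA sequencing libraries (TruSeq stranded mRNA) of lines described as mouse epiblast stem cells were compared in 4 groups, with 2 control, 3 Dkk1_KO, 2 IWP2 and 2 IWP2_removed libraries. The deposited tables of the authors give estimated counts per transcript, which are not whole where reads are shared between transcripts, and TPM, a length-scaled relative level, per transcript. The submitters' processing notes name Salmon, DESeq2 and edgeR without versions. Salmon made the deposited values, and the transcriptome build it used is not given in the sources used here. Estimated totals per library ran from 10849490 to 17892751 reads. Floors on zero counts cover counting error only, since PCR copies are not independent molecules.

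Transcripts were assigned to genes with the GENCODE vM21 annotation of mouse genome GRCm38. In every library 133399 of 133618 transcripts matched by stable identifier, of which 2166 carried another version number. The 219 unmatched transcripts held between 0.117% and 0.161% of the reads. Estimated counts were summed to 52609 genes and rounded, and 99 symbols belonged to more than 1 gene. Symbols, identifiers and coordinates are those of the annotation, and agreement of its coordinates with the build the authors used could be checked only through the transcript identifiers.

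Groups were compared with edgeR 4.0.16 in R 4.3.3, in 1 quasi-likelihood model with a mean per group over all 9 libraries and no replicate term. Library sizes were scaled by TMM, and filterByExpr left 18096 genes for testing. A gene was called where its Benjamini-Hochberg adjusted p over the genes tested was below 0.05. Common dispersion was 0.0524, a biological coefficient of variation of 0.229. Levels are CPM (counts scaled to a common library total) on the TMM scale, given as group mean and SD over libraries, and log2 fold changes come from the model with their standard error (SE). For a gene without a read in a group, a bound on the fold was computed from a floor of 3 counts over the whole group. Genes with 1 to 3 reads in a group are given as levels only.

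A collection of 31 gene lists, covering signalling, germ layers, pluripotency states, other cell types and cell state, was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry stood beside it, and p-values were adjusted over the 31 lists. For each list the number of called members was also counted after adjusting over the list alone. The comparisons, gene lists, tests, the threshold and the alternatives other than those named as added were chosen before the data were examined.

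Named genes followed a fixed rule. It took Dkk1, up to 4 called members of each list with the smallest adjusted p, or up to 2 members with the highest mean where a list had no call. It also took, per comparison, the 5 genes higher and the 5 genes lower with the largest fold change among called genes whose libraries did not overlap and whose higher group had a mean of at least 5 CPM, with predicted genes and pseudogenes passed over. Genes outside the rule are named as chosen after their values were seen.

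Comparisons that shared libraries were set beside simulated unchanged groups (20 draws). All 9 libraries were simulated from the control means as independent replicates, so the simulated comparisons shared simulated libraries. Their spread was that fitted to all 9 real libraries. After the data were examined, gene positions were used to compute the median log2 fold change in 239 windows of 10 Mb that held at least 15 genes with a mean of at least 5 CPM. Only the comparisons without Dkk1_KO were examined in this way. A window counted as shifted where its median lay past the largest median reached in 95% of 1000 shuffles of gene positions. The pipeline was tested on simulated data with the same group sizes. Simulated 4-fold changes were recovered in 72.8% of cases for Dkk1_KO against control, 46.9% for IWP2 against control and 55.6% for IWP2_removed against control. Recovery of 2-fold changes was 12%, 1.7% and 7.3%. Unchanged genes made up 8 of 88, 4 of 44 and 6 of 64 simulated calls. In this test of the pipeline all simulated libraries had the spread of the 6 libraries without Dkk1_KO, and their replicates were independent. These rates therefore need not hold for the model of the 9 real libraries.

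Alternatives were DESeq2 size factors or upper-quartile factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a stricter filter of 1 CPM, a transcript length offset, only the 2 groups compared, replicate number or the letter in the file names as a block, limma-trend on log2(TPM + 1), glmTreat against a fold of 1.5, and each library left out in turn. Alternatives added after seeing the data were the 6 libraries without Dkk1_KO, with or without a block, the Dkk1_KO libraries averaged to 1, and the calls without genes in shifted windows. SB431542 is named in the treatment protocol, but none of the groups analysed here was labelled with it. Each group is a single line by the series design, so line and condition are confounded, and the labels do not say whether replicates were separate cultures.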

Results

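Transcript levels were measured by RNA sequencing in lines described as epiblast stem cells, cells derived from the mouse epiblast and kept on inactivated embryonic fibroblasts as feeder cells. Of 26 core pluripotency and primed epiblast genes 14 lay below 50% of control in Dkk1_KO. Of these 9 lay below 10%, Pou5f1 and Nanog among them. Calls against Dkk1_KO therefore need not be changes within epiblast-like cells. All 4 lines received Activin A at 20 ng/mL and FGF2 at 10 ng/mL. The lines were an unmodified control (n = 2), a knockout of Dkk1, a secreted antagonist of Wnt signalling (Dkk1_KO, n = 3), a line kept in 5 µM IWP2, which blocks Wnt secretion through Porcupine (IWP2, n = 2), and a line from which IWP2 was removed after derivation (IWP2_removed, n = 2). Estimated reads per library, in replicate order, were 10849490 and 15618539 for control, 15047092, 13834808 and 14889250 for Dkk1_KO, 16885451 and 17892751 for IWP2, and 15816711 and 16001561 for IWP2_removed. The first principal component held 76.1% of the variance. Dkk1_KO libraries correlated with each other at 0.99 and with libraries of the other groups at 0.81 to 0.847, while libraries of the other 3 groups correlated at 0.957 to 0.975 within a group and 0.944 to 0.979 between groups, across genes, which are not independent replicates. Median SD of log2 CPM between replicates was 0.087 in Dkk1_KO, against 0.217 in control, 0.339 in IWP2 and 0.204 in IWP2_removed. Chi-square per degree of freedom between replicate libraries, which counting error alone puts near 1, was 1.79 to 2.27 for Dkk1_KO pairs, 32.9 for control, 94.4 for IWP2 and 39.0 for IWP2_removed. The labels do not say whether the Dkk1_KO libraries came from separate cultures, and repeats of a single RNA sample are not excluded. In that case their SDs, the SEs and the calls that rest on n = 3 would leave out the variation between cultures. The model pools the spread over all 9 libraries, so SEs and calls of the comparisons without Dkk1_KO would also be affected.

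Dkk1 itself (ENSMUSG00000024868.8, chromosome 19, 30545863 to 30549665, minus strand, GRCm38) fell in the knockout. Its level was 7.86 ± 1.54 CPM in control (SD, n = 2) and 0.889 ± 0.221 CPM in Dkk1_KO (SD, n = 3), a log2 fold change of -3.13 ± 0.68 (SE, adjusted p = 0.00597). The 3 knockout libraries held 37 Dkk1 reads and the 2 control libraries 220. With the Dkk1_KO libraries averaged to 1, an alternative added after seeing the data, the call ended (adjusted p = 0.129, range over its alternatives 2.9e-08 to 0.129). In IWP2 the level was 1.62 ± 1.80 CPM (n = 2), which did not pass the test against control (log2 fold change -2.27 ± 0.73, adjusted p = 0.165). It did pass by DESeq2 (adjusted p = 0.0431), without a filter on low counts (0.00104) and without IWP2 replicate 1 (0.00799). IWP2_removed held 4.65 ± 1.69 CPM (n = 2), with an adjusted p of 0.787 against control.

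The comparison of Dkk1_KO with control asked what loss of this Wnt antagonist changed in the same medium, but line and knockout are confounded. Genes of trophoblast and extraembryonic ectoderm were the most raised group. Elf5, a transcription factor of the trophoblast lineage (chromosome 2, 103411688 to 103450989, plus strand), was at 308 ± 4.84 CPM in Dkk1_KO (SD, n = 3) and 0.182 ± 0.00594 CPM in control (SD, n = 2). Hand1, a factor of trophoblast giant cells and mesoderm (chromosome 11, 57828705 to 57832818, minus strand), was at 574 ± 8.73 CPM against 0.0891 ± 0.126 CPM. Cdx2, a factor of trophectoderm and posterior epiblast and a Wnt target, was at 88.0 ± 4.66 CPM against 0.329 ± 0.290 CPM, and the keratin Krt7 was at 190 ± 4.42 CPM against 2.48 ± 0.360 CPM. Log2 fold changes were 10.65 ± 0.25 for Elf5 (SE, adjusted p = 2.2e-07), 8.17 ± 0.48 for Cdx2 (7.34e-06), 6.24 ± 0.24 for Krt7 (1.23e-06) and 8.51 ± 0.23 for Bmp8b (5.29e-07). Of 17 measured members of the trophoblast list 15 rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 6.24 and a camera adjusted p of 6.82e-12. The call held with an adjusted p = 0.024 with an estimated correlation, and it was the 1 list of 31 in this comparison that did. By DESeq2 and at an unadjusted p under 0.05 no member of the list was lower either.

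**Figure D1:**
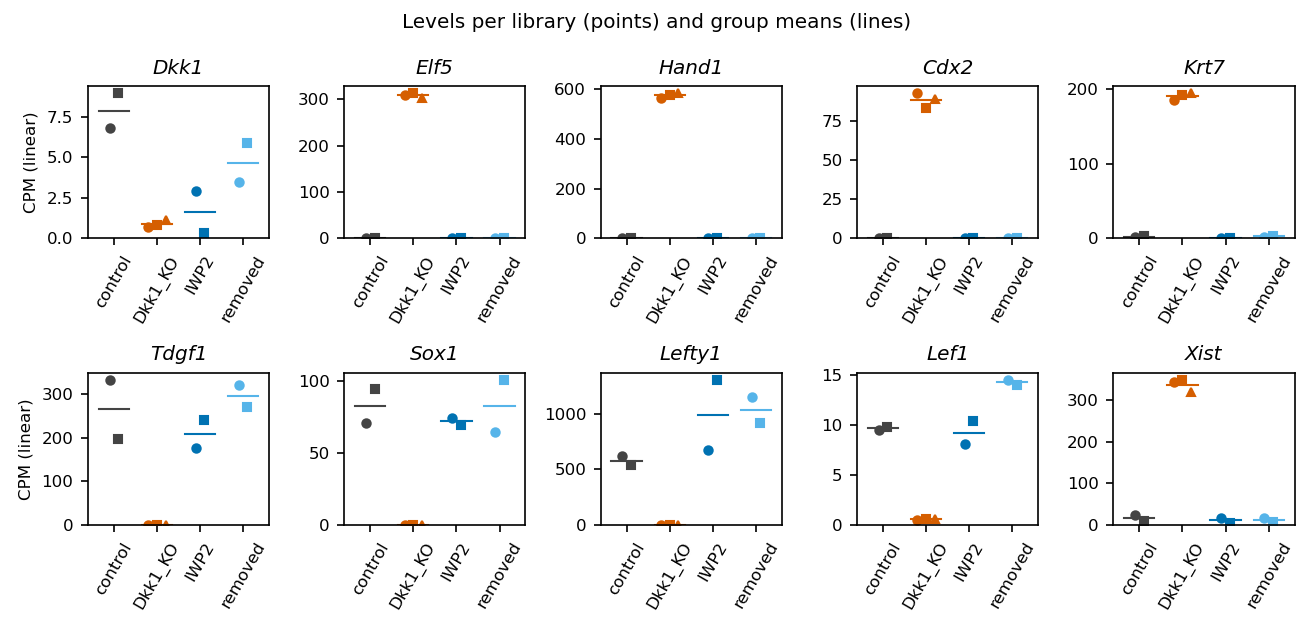
Levels of 10 genes in each library, with CPM on a linear vertical axis that starts at 0 and the 4 groups on the horizontal axis; points are libraries, marker shape is the replicate number and lines are group means. Elf5, Hand1, Cdx2, Krt7 and Xist were high in the 3 Dkk1_KO libraries, where Tdgf1, Sox1, Lefty1 and Lef1 were low.

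Several X-linked homeobox and germline genes had no read in either control library. Rhox9 was at least 1710-fold higher in Dkk1_KO, Rhox6 at least 1370-fold, Esx1 at least 675-fold and Mageb16 at least 659-fold. Rhox5, of the same homeobox cluster, reached 921 ± 11.7 CPM against 0.227 ± 0.0570 CPM (log2 fold change 11.98 ± 0.24, adjusted p = 2.03e-07). Among naive pluripotency genes 10 of 17 rose and 3 fell (10 and 3 adjusted over the list alone), with a camera adjusted p of 0.00201 and an adjusted p = 0.198 with an estimated correlation. They included Esrrb, a nuclear receptor of naive cells and trophoblast stem cells, at 268 ± 1.45 against 1.05 ± 0.0986 CPM, Klf5 at 88.7 ± 3.66 against 11.8 ± 1.01 CPM, and Zfp42, at least 454-fold higher. In the core pluripotency list 4 of 14 genes rose, among them Dppa4 (at least 746-fold), and 7 fell (4 and 7 adjusted over the list alone), with a camera adjusted p of 0.437. Surface ectoderm genes rose in 17 of 21 cases and fell in 1 (17 and 1 adjusted over the list alone), with a camera adjusted p of 5.96e-06 and an adjusted p = 0.235 with an estimated correlation. Its median log2 fold change was 3.96, or 3.50 with a gene absent from control at its bound. Examples were Grhl2, an epithelial factor, at 79.9 ± 0.808 against 2.35 ± 0.954 CPM, and Gata3 at 63.0 ± 2.06 against 1.70 ± 0.117 CPM. Of 19 genes of epithelial and mesenchymal state 11 rose and 4 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.01, adjusted p = 0.235 with an estimated correlation). The splicing regulator Esrp1 and the tight-junction genes Cldn4 and Cldn6 rose by log2 fold changes of 6.77 ± 0.32, 8.53 ± 0.52 and 4.73 ± 0.30, and the mesenchymal repressor Zeb1 fell (-2.70 ± 0.16).

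Many genes of the primed epiblast and of the germ layers were low in the same libraries, while others stayed near the control level or rose. Tdgf1, the Nodal co-receptor (chromosome 9, 110939603 to 110946158, minus strand), was at 0.338 ± 0.181 CPM in Dkk1_KO (n = 3) against 266 ± 95.6 CPM in control (n = 2), a log2 fold change of -9.59 ± 0.39 (adjusted p = 1.41e-06). Fgf15 was at 0.236 ± 0.143 against 132 ± 6.32 CPM (-9.06 ± 0.44). Pou5f1 at 1.39 against 457.5 CPM and Nanog at 2.00 against 169 CPM, both chosen after their values were seen, lay in the same direction. Of 26 core pluripotency and primed epiblast genes with at least 20 CPM in control 14 lay below 50% of control and 9 below 10%. Others, also chosen after their values were seen, did not, with Sox2 at 86.8%, Lin28a at 96.2%, Zfp281 at 108%, Dnmt1 at 97.6%, Dnmt3b at 331%, Krt18 at 3060% and Cdh1 at 4030% of control. Primed epiblast genes fell in 12 of 22 cases and rose in 5 (13 and 5 adjusted over the list alone), with a camera adjusted p of 0.0169 and an adjusted p = 0.412 with an estimated correlation. The neural ectoderm list had 20 lower and 5 higher of 32 (22 and 5 adjusted over the list alone), a camera adjusted p of 0.000733 and an adjusted p = 0.235 with an estimated correlation. It included Sox1, an early neural factor, at 0.240 ± 0.0356 against 82.6 ± 16.7 CPM, and En1 at 2.35 ± 0.349 against 45.6 ± 1.69 CPM. Of 14 genes of the node and anterior axial mesendoderm 12 fell and 0 rose (12 and 0 adjusted over the list alone), with a camera adjusted p of 1.42e-05 and an adjusted p = 0.287 with an estimated correlation. Otx2 and Foxa2 fell, with log2 fold changes of -7.39 ± 0.69 and -4.16 ± 0.51. Primitive streak genes fell in 10 of 17 cases and rose in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00201, adjusted p = 0.483 with an estimated correlation), and Fgf8 fell (log2 fold change -7.80 ± 0.50). Trh, a thyrotropin-releasing hormone precursor, was at 0.0234 against 720 CPM and Shh at 0.0487 against 53 CPM. Vtn, without a read in Dkk1_KO, was at least 391-fold lower, Mup6 at least 178-fold and Samd3 at least 105-fold. Mesoderm genes went both ways, 8 of 26 higher and 8 lower (9 and 8 adjusted over the list alone; camera adjusted p = 0.617). So did definitive endoderm genes, 6 of 16 higher and 8 lower (7 and 8 adjusted over the list alone; camera adjusted p = 0.49).

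Wnt pathway genes were more often lower than higher in Dkk1_KO. Many epiblast genes were also lower in these libraries, as were 16 of 32 feeder fibroblast genes (1 was higher). A change in Wnt signalling cannot be told apart from these differences here. Of 23 Wnt/beta-catenin target genes 12 fell and 3 rose (13 and 3 adjusted over the list alone), with a median log2 fold change of -0.78 and a camera adjusted p of 0.00248, which became an adjusted p = 0.235 with an estimated correlation. Lef1, a transcription factor and target of the pathway, fell from 9.64 ± 0.164 CPM (n = 2) to 0.578 ± 0.0774 CPM (n = 3), a log2 fold change of -4.04 ± 0.24 (adjusted p = 7.85e-06). Nkd1, a feedback inhibitor, fell from 30.5 ± 1.55 to 4.43 ± 0.162 CPM (-2.78 ± 0.17), and Sp8 was at 25.7 CPM in control and 0.0469 CPM in Dkk1_KO. Secreted Wnt antagonists fell in 11 of 15 cases and rose in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 0.000275, adjusted p = 0.198 with an estimated correlation), among them Sfrp1 (-2.92 ± 0.22), Shisa2 (-3.99 ± 0.39) and Wif1 (-8.39 ± 0.56). Wnt ligands and secretion genes split, with 9 of 19 lower and 3 higher (10 and 3 adjusted over the list alone; camera adjusted p = 0.227). Wnt7b rose from 2.67 to 389 CPM (log2 fold change 7.18 ± 0.41) and Wnt6 from 0.707 to 76.8 CPM (6.82 ± 0.73), while Wnt8a was at 71.9 CPM in control and 0.0725 CPM in Dkk1_KO.

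Nodal/Activin target genes fell in 9 of 16 cases and rose in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0155, adjusted p = 0.312 with an estimated correlation). Without control replicate 1 the camera adjusted p of this list was 0.0805. Lefty1, a Nodal inhibitor and target (chromosome 1, 180935022 to 180938400, plus strand), was at 1.18 ± 0.0426 against 577 ± 60.3 CPM (-8.93 ± 0.35), and Gdf3 fell too (-7.57 ± 0.51). BMP ligands and targets had 10 of 18 higher and 6 lower (10 and 7 adjusted over the list alone; camera adjusted p = 0.0716), with Smad6 at 2.93 ± 0.17, Smad7 at 2.88 ± 0.17 and Id2 at 2.74 ± 0.17 on the log2 scale. Of 16 Notch pathway genes 10 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.00499, adjusted p = 0.355 with an estimated correlation), and Notch3 fell (-1.93 ± 0.14). FGF/ERK target genes had a median log2 fold change of 0.31 and a mean of -0.28, so that their sign differed, with a camera adjusted p of 0.743.

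Markers of feeder cells, of chromosomal sex and of imprinting also differed. Feeder fibroblast genes fell in 16 of 32 cases and rose in 1 (18 and 1 adjusted over the list alone; camera adjusted p = 0.00201, adjusted p = 0.312 with an estimated correlation). The fibroblast collagen Col3a1 went from 695 ± 237 CPM to 176 ± 3.06 CPM and the proteoglycan Dcn from 85.5 ± 26.7 to 5.78 ± 0.400 CPM. Xist, the RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254, minus strand), stood at 1990% of control, at 337 against 16.9 CPM. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d stood at 2.02%, 2.61%, 2.47% and 8.54% of control. In the list of these 5 sex-linked genes 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.00447, adjusted p = 0.235 with an estimated correlation). Imprinted genes fell in 16 of 26 cases and rose in 4 (17 and 4 adjusted over the list alone; camera adjusted p = 0.00201, adjusted p = 0.306 with an estimated correlation), among them Rian (-3.57 ± 0.13) and Meg3 (-2.88 ± 0.15) of one imprinted cluster.

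Across all 18096 genes 3857 were higher and 4161 lower in Dkk1_KO than in control, of which 2399 and 2947 differed at least 2-fold. With the Dkk1_KO libraries, which may be repeats of a single sample, averaged to 1 there were 1355 higher and 1369 lower genes. Limma-trend called 2550 higher and 3937 lower, so 39.3% of its calls were higher against 48.1%, and a test against a fold of 1.5 called 2246 higher and 2686 lower. Of the genes named for this comparison by the rule, 13 lost their call with the averaged libraries, and of these Dkk1 is the 1 named here. Upper-quartile scaling moved the median of all genes to -0.1 and limma-trend to -0.135, against -0.03, and no called gene changed sign with upper-quartile scaling, while 61 did with limma-trend and 39 with a length offset.

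The comparison of IWP2 with control asked what a block of Wnt secretion changed. Gdf3, a Nodal-related ligand of the epiblast (chromosome 6, 122605403 to 122610087, minus strand), was at 1.65 ± 0.110 CPM in IWP2 (SD, n = 2) and 38.1 ± 8.38 CPM in control (SD, n = 2), a log2 fold change of -4.52 ± 0.46 (SE, adjusted p = 0.00382). Acsf2, an acyl-CoA synthetase, fell from 45.3 ± 16.5 to 1.53 ± 0.596 CPM (-4.88 ± 0.34, adjusted p = 0.0015), and the carbonic anhydrase Car4 (chromosome 11, 84957786 to 84966044, plus strand) from 116 ± 48.0 to 0.707 ± 0.179 CPM (-7.34 ± 0.69, 0.00374). Cyp26a1, which degrades retinoic acid, fell from 19.8 ± 6.31 to 3.49 ± 0.0939 CPM (-2.50 ± 0.27, 0.00438). Tnnt1, a troponin, rose from 7.90 ± 2.98 to 95.6 ± 25.8 CPM (3.58 ± 0.29, 0.00229) and Dcx, a protein of migrating neurons, from 13.1 ± 0.792 to 134 ± 67.8 CPM (3.35 ± 0.40, 0.00649). Hoxb9 rose from 6.89 ± 0.957 to 28.8 ± 5.98 CPM (2.06 ± 0.24, 0.00649), and the receptor gene Kit from 25 ± 0.662 to 53.1 ± 6.08 CPM (1.09 ± 0.15, 0.015). The imprinted genes H19 (chromosome 7, 142575529 to 142578143, minus strand) and Nnat (chromosome 2, 157560078 to 157562522, plus strand) moved apart, H19 from 2637 ± 643 to 496 ± 206 CPM (-2.41 ± 0.32, 0.0123) and Nnat from 22.1 ± 11.8 to 331 ± 169 CPM (3.91 ± 0.45, 0.00615). Further genes by the rule were the protocadherin Pcdha7 (-5.14 ± 0.69) and the transcription factor Gata4 (-2.98 ± 0.52), both lower, and the transcription factor Six2 (3.48 ± 0.49), higher.

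**Figure D2:**
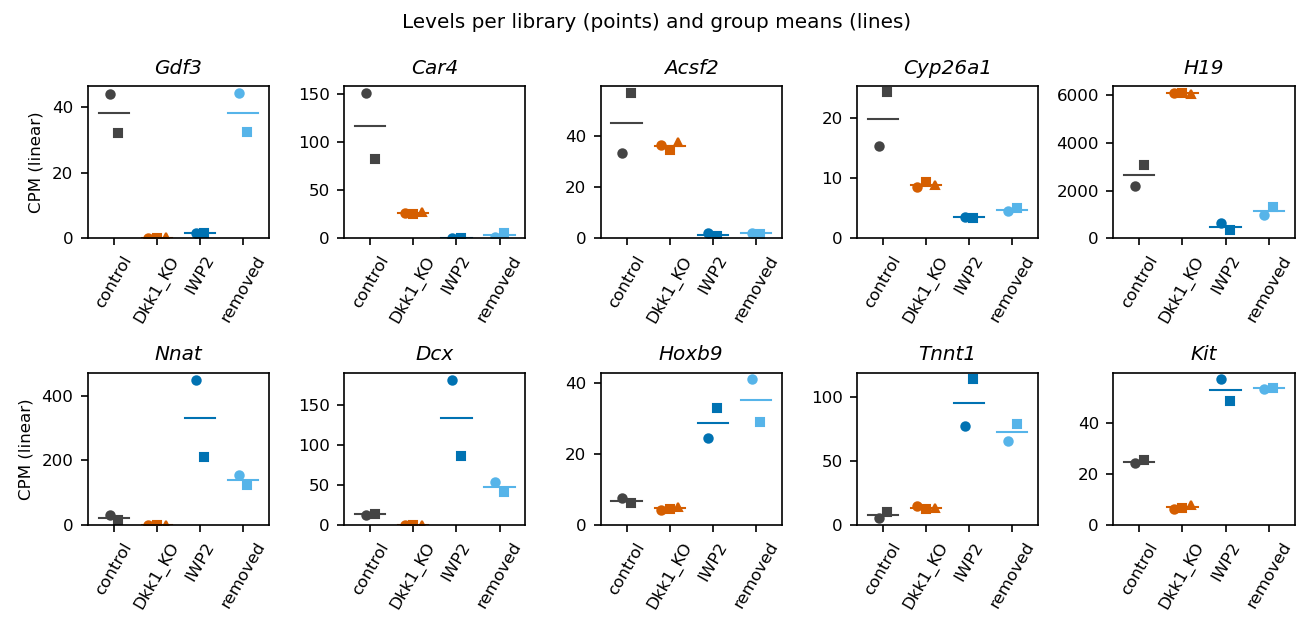
Levels of 10 genes in each library, with CPM on a linear vertical axis that starts at 0 and the 4 groups on the horizontal axis; points are libraries, marker shape is the replicate number and lines are group means. Gdf3 was low in both IWP2 libraries (1.65 CPM on average) and near the control level in both IWP2_removed libraries (38.3 CPM), while Tnnt1, Hoxb9 and Kit were above control in both groups.

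Wnt target genes were not called in this comparison. With edgeR 0 of 23 Wnt/beta-catenin target genes passed, 1 higher and 0 lower passed adjusted over the list alone, 2 higher and 3 lower had an unadjusted p under 0.05, and DESeq2 called 1 higher and 1 lower (camera adjusted p = 0.0783). Ccnd1 was at 291 ± 78.0 CPM in IWP2 and 332 ± 145 CPM in control (log2 fold change -0.19 ± 0.37, adjusted p = 0.865), and Fzd7 at 75 ± 15.6 and 93.5 ± 15.6 CPM (-0.32 ± 0.19, 0.478). The streak gene T was at 82.2 ± 76.2 and 78.0 ± 35 CPM (0.08 ± 0.62, 0.974). Definitive endoderm genes were lower as a list, with 1 of 16 lower and 0 higher (3 and 0 adjusted over the list alone) and a camera adjusted p of 2.24e-05, against an adjusted p = 0.487 with an estimated correlation. Feeder fibroblast genes were lower as a list as well, with 1 of 32 lower (3 adjusted over the list alone; camera adjusted p = 0.000318, adjusted p = 0.487 with an estimated correlation), and Lox, the called member, fell from 205.5 ± 2.18 to 109 ± 2.25 CPM. Extraembryonic endoderm genes had 1 of 16 lower and 0 higher (1 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.002, adjusted p = 0.548 with an estimated correlation). Neural ectoderm genes were higher as a list, with 1 of 32 higher, the gene Dcx, and 10 higher adjusted over the list alone (camera adjusted p = 0.00384, adjusted p = 0.487 with an estimated correlation). For the node list edgeR called 0 of 14, with 0 higher and 5 lower at an unadjusted p under 0.05, 0 higher and 2 lower by DESeq2 and 1 lower adjusted over the list alone (camera adjusted p = 0.00232, adjusted p = 0.623 with an estimated correlation). For secreted Wnt antagonists edgeR called 0 of 15, with 1 higher and 4 lower at an unadjusted p under 0.05, 0 higher and 2 lower by DESeq2 and 1 lower adjusted over the list alone (camera adjusted p = 0.0431, adjusted p = 0.487 with an estimated correlation). Epithelial and mesenchymal state genes had 0 of 19 called by edgeR, 1 higher and 6 lower at an unadjusted p under 0.05, 1 higher and 2 lower by DESeq2 and 1 higher adjusted over the list alone (camera adjusted p = 0.0345, adjusted p = 0.487 with an estimated correlation). Without IWP2 replicate 1 the camera adjusted p of the neural list was 0.22, and without IWP2 replicate 2 it was 0.305 for the node, 0.204 for extraembryonic endoderm, 0.313 for the antagonists and 0.204 for the epithelial list. The antagonist call also ended without control replicate 1 (0.142) and without Dkk1_KO replicate 2 (0.0512), and the epithelial call without control replicate 2 (0.0846). Imprinted genes had 3 of 26 higher and 2 lower (4 and 7 adjusted over the list alone; camera adjusted p = 0.181).

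In total 230 genes were higher and 166 lower in IWP2 than in control, and 2972 genes had an unadjusted p under 0.05. These counts depended on which libraries were in the model. With all 9 libraries a replicate block gave 190 and 155 and a block by the letter in the file names 234 and 169. In the 6 libraries without Dkk1_KO 6 genes were higher and 6 lower, all 12 also called with 9 libraries, among them Gdf3, Acsf2, Tnnt1, Pcdha7 and Zfp984. The same 6 libraries with replicate number as a block gave 260 and 188. With the Dkk1_KO libraries averaged to 1 there were 5 and 5, and with only the 2 groups compared 0 and 1. The count ran from 26 higher and 44 lower without control replicate 2 to 1147 and 1285 without IWP2 replicate 1. It was 50 and 79 without control replicate 1, 495 and 221 without IWP2 replicate 2, and 58 and 56, 47 and 54, and 56 and 59 without Dkk1_KO replicates 1, 2 and 3. DESeq2 called 591 and 403, no filter on low counts gave 685 and 535, a length offset 80 and 89, limma-trend 94 and 125, and a test against a fold of 1.5 called 40 and 57. Of the genes described, Gdf3, Acsf2 and Tnnt1 lost their call with only the 2 groups compared (adjusted p = 0.0522, 0.0815 and 0.0815, the highest over their alternatives, with lowest values of 5.77e-32, 5e-37 and 3.81e-27) and kept it in their other 23 alternatives. In the 6 libraries without Dkk1_KO the adjusted p was 0.0561 for Car4 and Dcx, 0.0888 for Cyp26a1 and Hoxb9, 0.0779 for Nnat, 0.13 for H19, 0.121 for Six2, 0.139 for Kit, 0.157 for Lox and 0.267 for Gata4. Without control replicate 2 it was 0.0735 for H19, 0.0712 for Hoxb9 and Pcdha7, 0.0507 for Nnat, 0.0802 for Dcx, 0.0547 for Lox, 0.109 for Six2, 0.0915 for Kit and 0.107 for Gata4. Without control replicate 1 it was 0.0692 for Dcx, 0.0743 for Six2, 0.0839 for Kit and 0.104 for Gata4. With only the 2 groups compared the single call was Car4. A length offset and limma-trend ended the calls of Kit (0.0527 and 0.0974) and Gata4 (0.172 and 0.267), and a test against a fold of 1.5 those of Kit (0.109), Gata4 (0.0693) and Lox (0.143). Kit also lost its call without Dkk1_KO replicate 2 (0.0536) and Gata4 without each of the 3 Dkk1_KO libraries (0.079, 0.0795 and 0.0784).

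Neighbouring genes were shifted together along several chromosomes in the comparisons of IWP2, IWP2_removed and control with each other, a pattern found after the data were examined. Comparisons with Dkk1_KO were not examined for it. In IWP2 against control 19 of 239 windows of 10 Mb had a median log2 fold change past the limit of 0.325 from shuffled positions. The largest blocks were higher, at chromosome 1 from 150 to 200 Mb (median 0.54, 86.4% of 242 genes above 0), chromosome 6 from 40 to 60 Mb (0.68, 88.9% of 81 genes) and chromosome 13 from 10 to 100 Mb (0.45, 86.1% of 346 genes). In IWP2_removed against control 19 windows passed a limit of 0.282. Among them chromosome 1 from 150 to 200 Mb (0.45) and chromosome 6 from 40 to 60 Mb (0.65) were higher, as was chromosome 3 from 90 to 140 Mb (0.55). Chromosome 3 from 140 to 160 Mb (-0.74) and chromosome 13 from 100 to 120 Mb (-0.70) were lower. Between IWP2_removed and IWP2 24 windows passed a limit of 0.247, with chromosome 3 from 90 to 140 Mb higher (0.58) and from 140 to 160 Mb lower (-0.76), chromosome 12 from 70 to 120 Mb lower (-0.46) and chromosome 13 from 0 to 120 Mb lower (-0.48). The blocks on chromosome 1 from 150 to 200 Mb and chromosome 6 from 40 to 60 Mb were not shifted there. They were similar in both lines against control, so they may lie in the control line instead. Shifted windows held 24.2% of the calls of IWP2 against control but 7.5% of tested genes, and 43.6% of the calls of IWP2_removed against control but 7.07% of tested genes. With p-values adjusted anew over the genes outside these windows, 118 higher and 134 lower genes were called for IWP2 and 31 and 52 for IWP2_removed, each against control. In the full adjustment 96 of 396 and 99 of 227 calls lay in the windows, so the new adjustment also ended calls outside them.

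**Figure D3:**
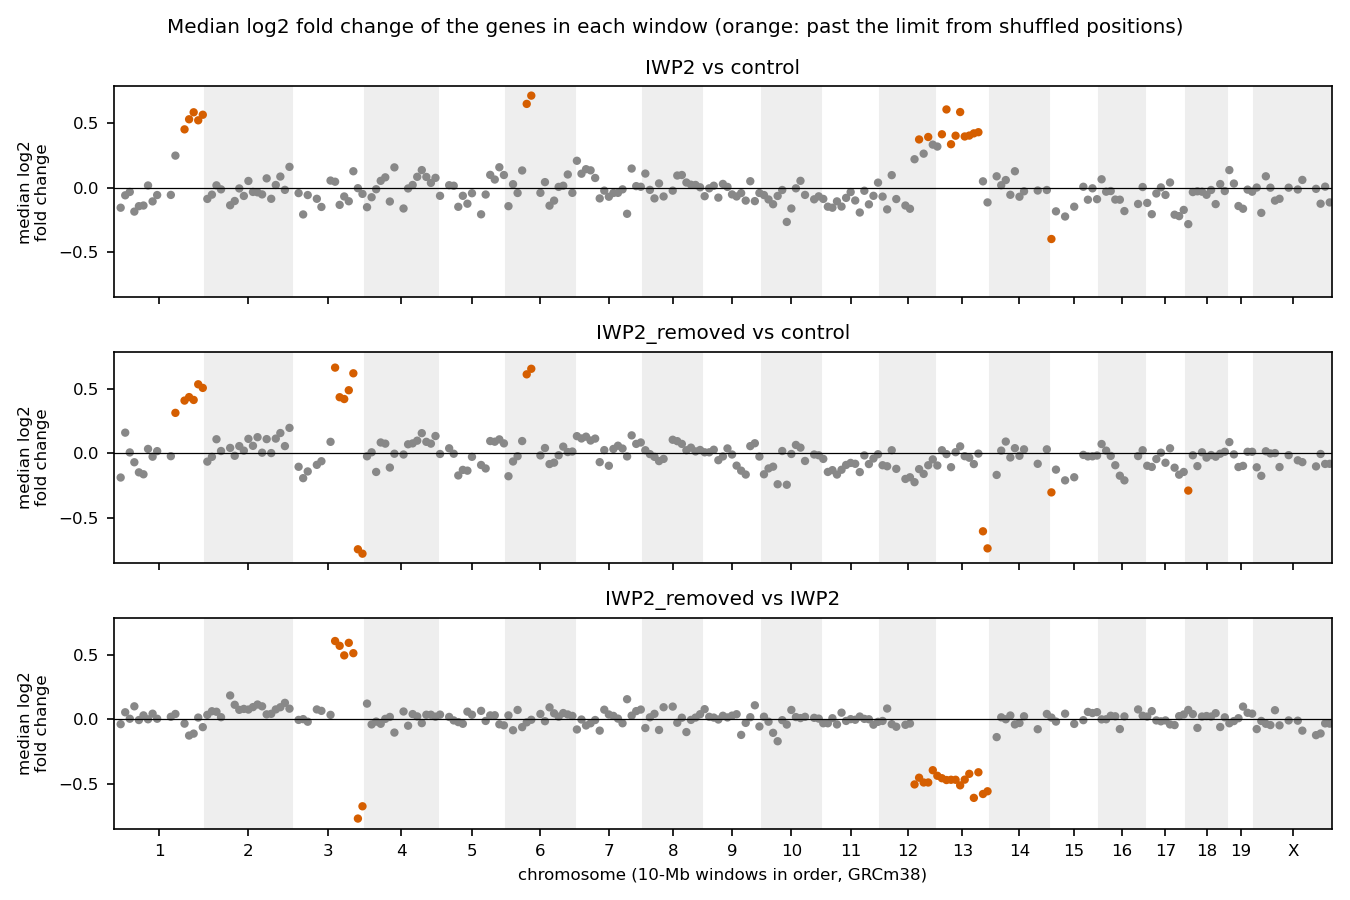
Median log2 fold change of the genes in each 10-Mb window (vertical axis) in order along the chromosomes (horizontal axis) for IWP2 against control, IWP2_removed against control and IWP2_removed against IWP2. Each point is a window, and orange points are the 19, 19 and 24 windows past the limit from shuffled gene positions.

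Removal of the inhibitor after derivation was read from IWP2_removed against IWP2. Gdf3 stood at 38.3 ± 8.27 CPM in IWP2_removed (SD, n = 2) and 1.65 ± 0.110 CPM in IWP2 (SD, n = 2), a log2 fold change of 4.53 ± 0.46 (SE, adjusted p = 0.0281), next to 38.1 CPM in control. The zinc finger gene Zfp984 went from 1.57 ± 0.249 to 7.80 ± 0.338 CPM (2.31 ± 0.21, 0.0178) and the olfactory receptor gene Olfr784 from 8.45 ± 1.10 to 38.4 ± 5.77 CPM (2.18 ± 0.18, 0.0171), against 16.1 and 38.9 CPM in control. Ttc30a1, of the ciliary transport machinery, fell from 9.41 ± 0.810 to 1.70 ± 0.00139 CPM (-2.47 ± 0.26, 0.0321) with 9.54 CPM in control. Genes in shifted windows were also called, Rtn1 (-2.36 ± 0.28), Gprin1 (-2.37 ± 0.27) and Ube2ql1 (-2.39 ± 0.29) lower and Pip5k1a (1.07 ± 0.12) and Snx27 (0.98 ± 0.12) higher. In all, 7 genes were higher and 4 lower, with 1754 at an unadjusted p under 0.05. The remaining called genes, Gm42047 and Gm45322, are predicted genes named after their values were seen. Of the 11 genes 7 reversed their change in IWP2 against control (Gdf3, Zfp984, Olfr784, Gm45322, Rtn1, Gprin1 and Ube2ql1), where independent calls would share 0.12, a value that ignores the shared IWP2 libraries. Simulated unchanged groups shared 0, which their lack of changes fixes in advance. Neither value is a chance level for this count. The IWP2 libraries stand in both comparisons with opposite sign, which alone makes the fold changes run opposite, and across all tested genes their correlation was -0.503 against -0.486 with simulated unchanged groups (covariance -0.271 against -0.113). The simulated replicates lacked the deviation that real replicates of the same number shared. Their spread came from all 9 libraries, of which the Dkk1_KO replicates varied least, so the simulated covariance may be too small.

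By camera at the preset correlation 4 gene lists differed with removal, with few single calls, but 0 passed with an estimated correlation or by fry. The feeder and neural lists went the other way in IWP2 against control. That comparison shares the IWP2 libraries, which alone can make lists run opposite. Nodal/Activin target genes were higher, with 1 of 16 called, the gene Gdf3 (2 adjusted over the list alone; camera adjusted p = 0.00118, adjusted p = 0.749 with an estimated correlation). Feeder fibroblast genes were higher as a list with 0 of 32 called by edgeR (0 adjusted over the list alone, 6 higher and 0 lower at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 0.000176, adjusted p = 0.749 with an estimated correlation). The p53 response genes were higher with 0 of 20 called by edgeR (0 adjusted over the list alone, 4 higher and 0 lower at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 0.000278, adjusted p = 0.765 with an estimated correlation). Neural ectoderm genes were lower with 0 of 32 called by edgeR (0 adjusted over the list alone, 0 higher and 6 lower at an unadjusted p under 0.05, 0 higher and 1 lower by DESeq2; camera adjusted p = 0.00127, adjusted p = 0.749 with an estimated correlation). Without IWP2_removed replicate 1 the camera adjusted p was 0.0586 for feeder, 0.32 for p53 response and 0.0513 for neural genes. Without IWP2 replicate 1 it was 0.317 for neural and 0.0562 for Nodal/Activin genes, and without IWP2 replicate 2 it was 0.0548 for feeder genes. Of 23 Wnt/beta-catenin target genes edgeR called 0 (0 adjusted over the list alone), with 2 higher and 0 lower at an unadjusted p under 0.05 and 0 by DESeq2. Single calls of removal depended on single libraries. In the 6 libraries without Dkk1_KO and with the Dkk1_KO libraries averaged to 1, 1 gene was higher and 0 lower, and in the former it was Gdf3. The 6 libraries with replicate number as a block gave 2 and 0, as did all 9 with that block. With only the 2 groups compared there were 0 of either direction, with 663 at an unadjusted p under 0.05. Counts of higher and lower genes were 1 and 0 without Dkk1_KO replicate 1, 0 and 0 without Dkk1_KO replicate 2, Dkk1_KO replicate 3, IWP2_removed replicate 1 or IWP2_removed replicate 2, and 2 and 0 without either control library. They were 195 and 200 without IWP2 replicate 1 and 137 and 317 without IWP2 replicate 2. DESeq2 called 147 and 186, no filter on low counts gave 202 and 212, and a stricter filter 12 and 9. With a length offset or a test against a fold of 1.5 they were 4 and 0, and with limma-trend 3 and 2. For Gdf3 the adjusted p was 0.0892 and 0.0814 without control replicates 1 and 2, 0.135 and 0.0701 without Dkk1_KO replicates 2 and 3, and 0.196 and 0.131 without IWP2_removed replicates 1 and 2. Zfp984, Olfr784, Ttc30a1, Rtn1, Ube2ql1, Gprin1, Snx27 and Pip5k1a lost their calls without each Dkk1_KO and each IWP2_removed library, with adjusted p from 0.0776 to 0.267, and all of these but Olfr784 without either control library (0.0611 to 0.0938).

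IWP2_removed and control shared their medium and differed in their history of inhibitor during derivation, and also as lines. Tnnt1 stood at 72.4 ± 9.72 CPM in IWP2_removed (SD, n = 2) against 7.90 ± 2.98 CPM in control (SD, n = 2), a log2 fold change of 3.18 ± 0.29 (SE, adjusted p = 0.00586). Hoxb9 was at 35.2 ± 8.57 against 6.89 CPM (2.35 ± 0.25, 0.00787), Kit at 53.7 ± 0.0296 against 25 CPM (1.11 ± 0.15, 0.0208) and Nnat at 139 ± 20.4 against 22.1 CPM (2.66 ± 0.43, 0.0312). Car4 was lower at 3.37 ± 3.05 against 116 CPM (-5.11 ± 0.59, 0.0102), as were Cyp26a1 at 4.78 ± 0.432 against 19.8 CPM (-2.05 ± 0.26, 0.0135), the sterol hydroxylase gene Cyp27a1 at 0.154 ± 0.0395 against 8.85 CPM (-5.78 ± 0.57, 0.00776) and the growth factor gene Igf2 at 587 ± 17.9 against 1401 CPM (-1.26 ± 0.23, 0.0441). Gbp2b, in a shifted window, was at 0.0617 CPM against 10.1 CPM. Of the calls in this comparison 120 were shared in direction with IWP2 against control, where independent calls would share 2.51. Simulated unchanged groups shared on average 0.05 or fewer in each direction. They hold few calls to share by construction, so this is no chance level. The 2 control libraries are common to both comparisons and cannot be split between them, so part of the sharing can come from them. Part can also come from chromosome blocks, since 43.6% of the calls here lay in shifted windows. Chromosome 1 from 150 to 200 Mb and chromosome 6 from 40 to 60 Mb were shifted in both comparisons.

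Imprinted genes were lower as a list in IWP2_removed than in control, with 1 of 26 higher and 1 lower (1 and 5 adjusted over the list alone; camera adjusted p = 0.00138, adjusted p = 0.667 with an estimated correlation). Definitive endoderm genes were lower with 0 of 16 called by edgeR (0 adjusted over the list alone, 0 higher and 8 lower at an unadjusted p under 0.05, 0 higher and 2 lower by DESeq2; camera adjusted p = 0.000177, adjusted p = 0.667 with an estimated correlation). Node genes were lower with 0 of 14 called by edgeR (2 lower adjusted over the list alone, 0 higher and 7 lower at an unadjusted p under 0.05, 0 higher and 3 lower by DESeq2; camera adjusted p = 0.00219, adjusted p = 0.667 with an estimated correlation). Cholesterol synthesis genes were higher as a list with 0 of 22 called by edgeR (1 lower adjusted over the list alone, 3 higher and 1 lower at an unadjusted p under 0.05, 0 higher and 1 lower by DESeq2; camera adjusted p = 0.0266, adjusted p = 0.667 with an estimated correlation). Epithelial and mesenchymal state genes (camera adjusted p = 0.044, adjusted p = 0.667 with an estimated correlation) had 0 of 19 called by edgeR, 0 adjusted over the list alone, 0 higher and 6 lower at an unadjusted p under 0.05 and 0 higher and 2 lower by DESeq2. Nodal/Activin target genes had 1 of 16 higher and 0 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.0459, adjusted p = 0.667 with an estimated correlation). Without control replicate 2 the camera adjusted p was 0.0875 for cholesterol, 0.107 for epithelial and 0.708 for Nodal/Activin genes. Without IWP2_removed replicate 1 it was 0.0654 for epithelial and 0.106 for Nodal/Activin genes, and without IWP2_removed replicate 2 it was 0.408 for cholesterol genes.

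In total 121 genes were higher and 106 lower in IWP2_removed than in control, with 2154 at an unadjusted p under 0.05. In the 6 libraries without Dkk1_KO, and with the Dkk1_KO libraries averaged to 1, 1 was higher and 0 lower, and with only the 2 groups compared 5 and 5. The 6 libraries with replicate number as a block gave 99 and 103. Counts were 11 and 26 without control replicate 1, 11 and 20 without control replicate 2, 8 and 6 without IWP2_removed replicate 1 and 12 and 8 without IWP2_removed replicate 2. They were 17 and 18, 12 and 17, and 13 and 19 without Dkk1_KO replicates 1, 2 and 3, and 364 and 366, and 376 and 362, without IWP2 replicates 1 and 2. DESeq2 called 315 and 312, no filter on low counts gave 362 and 370, a length offset 36 and 43, a replicate block 71 and 64, limma-trend 37 and 67, and a test against a fold of 1.5 called 18 and 29. In the 6 libraries without Dkk1_KO the adjusted p was 0.0981 for Tnnt1, 0.135 for Hoxb9, 0.143 for Car4, 0.13 for Cyp27a1, 0.229 for Kit and Cyp26a1, 0.242 for Nnat and 0.333 for Igf2. Tnnt1 kept its call with each of the 9 libraries left out in turn. Without IWP2_removed replicate 1 the adjusted p was 0.0536 for Hoxb9, 0.0692 for Cyp27a1, 0.106 for Kit and Cyp26a1, 0.137 for Nnat and 0.201 for Igf2. Without IWP2_removed replicate 2 it was 0.0742 for Cyp27a1, 0.123 for Kit and Nnat, 0.101 for Cyp26a1 and 0.217 for Igf2. Without control replicate 1 it was 0.0531 for Car4, 0.0504 for Hoxb9, 0.107 for Kit and 0.0628 for Nnat and Igf2. Without control replicate 2 it was 0.0758 for Hoxb9 and Cyp26a1, 0.128 for Kit, 0.159 for Nnat and 0.186 for Igf2. Leaving out a Dkk1_KO library ended the calls of Kit (0.0565, 0.0717 and 0.0592 for replicates 1, 2 and 3), Cyp26a1 (0.0552, 0.0587 and 0.0592), Nnat (0.0927, 0.0909 and 0.0925) and Igf2 (0.13, 0.134 and 0.126). A test against a fold of 1.5 ended the calls of Kit (0.174), Nnat (0.0888) and Igf2 (0.273), limma-trend those of Kit (0.14), Nnat (0.0851) and Igf2 (0.0677), and a length offset those of Kit (0.0929) and Igf2 (0.0643). Igf2 was also not called with a replicate block (0.0764) or without genes in shifted windows (0.0723).

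The differences of Dkk1_KO and of IWP2 from control were compared directly in Dkk1_KO against IWP2, which is the test between them. An effect of the knockout cannot be told apart from other differences of its line. Xist stood at 1990% and Eif2s3y at 2.61% of control in that line. Krt7 stood at 190 ± 4.42 CPM in Dkk1_KO (SD, n = 3) and 0.791 ± 0.297 CPM in IWP2 (SD, n = 2), a log2 fold change of 7.89 ± 0.27 (SE, adjusted p = 6.1e-07). Elf5 was at 308 and 0.0290 CPM, and Hand1 at 574 and 0.0568 CPM. Lower in the knockout than in IWP2 were Lefty1 (-9.70 ± 0.35, 7.33e-07), Tdgf1 (-9.24 ± 0.39, 1.13e-06), Sox1 (-8.18 ± 0.31, 7.61e-07), T (-4.79 ± 0.65, 0.000426), Lef1 (-3.98 ± 0.24, 5.69e-06), Nkd1 (-2.73 ± 0.17, 5.6e-06) and Kit (-2.94 ± 0.14, 2.28e-06). Dkk1 did not pass (-0.86 ± 0.71, adjusted p = 0.344), except without IWP2 replicate 2 (0.012). Of 17 trophoblast genes 16 were higher and 0 lower (17 and 0 adjusted over the list alone; camera adjusted p = 7.46e-11, adjusted p = 0.0297 with an estimated correlation). Wnt/beta-catenin target genes were lower in 10 of 23 cases and higher in 3 (11 and 3 adjusted over the list alone; camera adjusted p = 0.0484, adjusted p = 0.469 with an estimated correlation). Its camera adjusted p was 0.055 and 0.0547 without control replicates 1 and 2, 0.0526 without Dkk1_KO replicate 1, 0.0529 and 0.0506 without IWP2_removed replicates 1 and 2, and 0.226 without IWP2 replicate 1. The comparison called 4385 genes higher and 4930 lower, against 1933 and 1944 with the Dkk1_KO libraries averaged to 1 and 2737 and 3274 in a test against a fold of 1.5.

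Across genes the log2 fold changes of Dkk1_KO and of IWP2, both against control, correlated at 0.007, where simulated unchanged groups that shared simulated control libraries correlated at 0.566 on average (covariance 0.011 against 0.122). The simulated groups held no changes, whereas 8018 genes were called in Dkk1_KO against control, so 0.566 is no chance level for this correlation. Genes called in the same direction in both numbered 103, against 87.2 for independent calls, and genes called in opposite directions 182, against 88.3. The values for independent calls ignore the shared control libraries, so they are no chance levels either. Gdf3 was lower than control in both, and Kit was lower in the knockout (-1.85 ± 0.14, adjusted p = 2.68e-05) and higher in IWP2. Without control replicate 1 the correlation was 0.188, without control replicate 2 it was 0.235, by DESeq2 it was 0.238 and with no filter on low counts 0.296. Genes are not independent replicates, and no p is given for these values.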

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

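Tests chosen only after the result was seen were the 6 libraries without Dkk1_KO, those with a replicate block, the Dkk1_KO libraries averaged to 1, and the calls without genes in shifted windows. Of 424 results for single named genes 283 were called, and 208 of these kept their call in every alternative run. Over 9445 values for single genes under an alternative, 8682 kept direction and side of the threshold, 526 lost the call and 50 gained one. Another 185 changed direction without a call in either fit. The last 2 changed direction with a call under the alternative. Both were in Notch1 without IWP2 replicate 1. Its log2 fold change in IWP2 against control was 0.10 with all libraries and ran from -1.16 to 0.75 with a library left out, and in IWP2_removed against IWP2 it was -0.28 and ran from -0.93 to 0.97, and the cause was not tested.

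Counts below are genes higher and then lower. With the Dkk1_KO libraries averaged to 1 they were 1355 and 1369 for Dkk1_KO against control, 5 and 5 for IWP2 against control, 1 and 0 for IWP2_removed against IWP2, 1 and 0 for IWP2_removed against control, and 1933 and 1944 for Dkk1_KO against IWP2. In the same order a test against a fold of 1.5, which asks for a larger change by construction, gave 2246 and 2686, 40 and 57, 4 and 0, 18 and 29, and 2737 and 3274. Limma-trend called 2550 higher in Dkk1_KO against control (3937 lower, within 1.5 times), which lowered the share of higher genes from 48.1% to 39.3%. For the 3 comparisons without Dkk1_KO, in the order IWP2 against control, IWP2_removed against IWP2 and IWP2_removed against control, it called 94 higher (125 lower, within 1.5 times), 3 and 2, and 37 and 67. In that order the 6 libraries without Dkk1_KO gave 6 and 6, 1 and 0, and 1 and 0, and only the 2 groups compared gave 0 and 1, 0 and 0, and 5 and 5. Both leave fewer libraries to estimate the spread, and both leave out the Dkk1_KO libraries. Median SD of log2 CPM between replicates was 0.087 in Dkk1_KO and 0.204 to 0.339 in the other groups. Neither was varied alone. Without 1 Dkk1_KO library the counts of IWP2 against control were 58 and 56, 47 and 54, and 56 and 59. They fell less without 1 IWP2_removed library, a group also outside this comparison, so the number of libraries alone does not explain the fall. The edgeR counts at an unadjusted p under 0.05 with only the 2 groups compared were 1212, 663 and 1666. DESeq2 called 591 and 403, 147 and 186, and 315 and 312. No filter on low counts gave 685 and 535, 202 and 212, and 362 and 370. A length offset gave 80 and 89, 4 and 0, and 36 and 43. A replicate block gave 2 and 0 for IWP2_removed against IWP2 and 71 and 64 for IWP2_removed against control, and a block by the letter in the file names gave 3 and 0 for the former. The 6 libraries with a block gave 260 and 188, 2 and 0, and 99 and 103. With a block in both fits, leaving out Dkk1_KO thus raised the counts against control, from 190 and 155 for IWP2 and from 71 and 64 for IWP2_removed. A stricter filter gave 12 and 9 for IWP2_removed against IWP2. With p-values adjusted anew without genes in shifted windows, 118 were higher in IWP2 against control, 1 was lower in IWP2_removed against IWP2, and 31 and 52 differed in IWP2_removed against control. The causes of the differences between tools, filters and offsets were not tested.

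Leaving out each library in turn gave 2911 to 4794 higher and 3140 to 4978 lower genes for Dkk1_KO against control, 26 to 1147 and 44 to 1285 for IWP2 against control, 0 to 195 and 0 to 317 for IWP2_removed against IWP2, 8 to 376 and 6 to 366 for IWP2_removed against control, and 3513 to 4776 and 3928 to 4968 for Dkk1_KO against IWP2. Where this left a group with 1 library, that library was assumed to vary like the other groups. The number of gene lists past the threshold by camera was 15, 7, 4, 6 and 16 in the 5 comparisons, with Dkk1_KO against control first and Dkk1_KO against IWP2 last. It ran from 14 to 16, 6 to 13, 4 to 12, 4 to 10 and 14 to 17 with a library left out, and was 1, 0, 0, 0 and 1 with an estimated correlation. Fry, which tests a list without comparing it with other genes, passed 0, 0 and 0 lists in the 3 comparisons without Dkk1_KO and 21 lists in each of the others. The correlation of Dkk1_KO and IWP2 effects across genes was 0.007, 0.238 by DESeq2, 0.296 with no filter on low counts, -0.051 with a stricter filter, and -0.007 to 0.235 with a library left out. The number of genes that reversed the IWP2 effect on removal was 7, and it was 133 by DESeq2, 183 with no filter, 2 with a replicate block, 1 in the 6 libraries without Dkk1_KO, and 0 to 293 with a library left out.

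Depth limited genes of low level. With totals of 10849490 to 17892751 reads, a floor of 3 counts over the group lay at 0.11 CPM for control and 0.0722 CPM for Dkk1_KO. Simulated 2-fold changes were recovered in 1.7% of cases for IWP2 against control, so a missing call in that comparison does not exclude changes of that size.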

Other observations

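Of the tests below, only that of sequencing depth was chosen before its result was seen, and all others were chosen after. Replicates 1 and 2 differed the same way in control, IWP2 and IWP2_removed for a minority of the gene lists. Of 31 lists 14 had a median log2 ratio of 1 sign in the 3 groups, and 4 of these also lay past 0.3 with both quartiles on that side in each group, which are the lists given next. The other 17 differed in sign or had a median of 0, such as definitive endoderm (0.01, 1.42 and -0.07), neural ectoderm (-0.26, 0.58 and -0.11), core pluripotency (0.09, -0.68 and -0.25) and the Notch pathway (-0.27, 0.22 and -0.16). Glycolysis genes were lower in replicate 1 than in replicate 2, with median log2 ratios of -0.95 in control, -1.19 in IWP2 and -1.05 in IWP2_removed over 21 genes, and 1 of 21 genes was above 0 in each group. Genes of the integrated stress response were lower as well (-1.03, -1.88 and -1.26 over 17 genes). FGF/ERK target genes were higher in replicate 1 (0.90, 1.02 and 0.56 over 20 genes, with 19, 20 and 19 above 0), as were primitive streak genes (0.75, 1.47 and 0.84 over 17 genes). In Dkk1_KO the ratio of replicate 1 to 2 was 0.02 for glycolysis, 0.01 for the stress response and 0.02 for FGF/ERK targets.

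Trophoblast genes were high and epiblast genes low in the Dkk1_KO libraries, and of the 17 trophoblast genes 9 also stood in another list and 4 were at or above 5 CPM in control. Scaling of the libraries is argued against, since the lowest median log2 fold change of the trophoblast list over 3 scalings was 6.17. A minority of trophoblast cells in an epiblast culture was first tested by the median level of 26 epiblast genes of at least 20 CPM in control, which was 38.3% of control (bootstrap interval over genes 5.41 to 72.3) and left the question open, since the list holds genes that trophoblast may also express, such as Cdh1. A second test, chosen after the values per gene were seen, is against it, since 34.6% of these genes (9 of 26) lay below 10% of control, with Pou5f1 at 0.304% and Tdgf1 at 0.127%, whereas a minority of other cells would leave epiblast genes at a larger share of control. Libraries of another line than the label says cannot be told apart from an effect of the knockout, since Dkk1 stood at 11.3% of control, a level both allow, the knockout is a single line, and Xist at 1990% and Eif2s3y at 2.61% of control show that it differs from the control line in sex chromosomes.

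Blocks of neighbouring genes were shifted in the IWP2 and IWP2_removed libraries against control or against each other. Those on chromosome 1 from 150 to 200 Mb and chromosome 6 from 40 to 60 Mb were shifted against control in both lines. They were not shifted between the lines, so for them a difference in the control line is not excluded. Chance runs along the chromosomes are argued against by 19 windows of IWP2 against control past a limit that 95% of shuffles did not pass at all. By its labels IWP2_removed was without the inhibitor, and 19 windows were shifted there against control, whereas an effect of the inhibitor on the blocks in IWP2 was not tested. Gained or lost chromosome segments are a candidate explanation, since in windows picked on replicate 1 at least 79% of genes moved the same way in replicate 2, against 55.9% and 56.3% in other windows. The share of cells that would carry them was not tested. Another stable difference between lines, such as strain background, would pass the same test and stays open, and no DNA data were analysed here.

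Replicates of the same number deviated together in control, IWP2 and IWP2_removed, with correlations of deviations across genes of 0.328, 0.453 and 0.505 between pairs of groups and -0.049 to -0.027 with Dkk1_KO. With 2 libraries in each of these groups, a group gives a single difference, and the numbering sets its sign. Alignment by the numbering alone is therefore not excluded, and genes are not independent replicates. Sequencing depth is argued against, since the lowest correlation was 0.328 after all 6 libraries were thinned to equal totals. A difference in feeder-cell share was not decided, since the median log2 ratio of replicate 1 to 2 over feeder genes was -0.187 in control (quartiles -0.548 to 0.238) and 0.229 and 0.251 in IWP2 and IWP2_removed, with members going both ways in each. A culture state shared by replicates of one number was not decided, since the lists that moved together were found from these same ratios and the labels do not say what such replicates share.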
